A study of Homo sapiens with 18 samples.

How the data were processed

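RNA from 18 human skin biopsies was labelled with biotin and hybridised to Affymetrix Human Gene 1.0 ST arrays, which carry probes along the whole length of each transcript, per the labels and the series' design text. The labels give 3 groups, lesional skin (6 biopsies), nonlesional skin of patients (7 biopsies) and normal skin of healthy donors (5 biopsies). Within a group each biopsy came from a different donor, per the labels.

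The deposited values are log2 expression made with RMA, and Partek is also named, both per the submitters' processing notes. Versions and parameters of RMA and Partek are not given in the sources used here. RMA corrects the background of each array, quantile normalizes the probes across arrays and fits 1 value per probe set, so the spread of values is made alike across arrays before any comparison. The table held 33297 rows with no missing value, between 3.10 and 14.1 on the log2 scale, and all columns matched a sample. The number of arrays limits the precision. Low values lie near the background of the array, where differences are compressed.

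Rows were named with the platform annotation, in which 19460 rows had 1 gene symbol, 1754 had several and 12083 had none. Symbols were compared with NCBI RefSeq's gene table of GRCh38.p14 through the Entrez number, which changed 0 symbols and left 31 without a match under their annotated name. No coordinates are given because the build behind the array annotation is not given in the sources used here. Rows with several symbols were not named, which removed genes of near-identical families such as TPSAB1 and TPSB2, and MS4A2 was not measured by a row of its own, so 2 of the 12 genes to be named in any case have no value. For 768 genes with more than 1 row the row with the highest mean over all arrays was used. XIST, TSIX, genes of the Y chromosome and genes often deleted in the germ line were left out of all tests, which removed 127 rows. The genes tested numbered 18383, with no filter on low values.

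Differences were tested with limma 3.58.1 in R 4.3.3. A model with 1 mean per group was fitted to all 18 arrays, which share 1 estimate of the spread, and moderated statistics were taken from eBayes with its default settings. Each of the 3 comparisons was adjusted by the Benjamini-Hochberg method over all genes tested, and a gene is said to have risen, fallen or been called at an adjusted p under 0.05. A second count required at least a 1.5-fold difference. Differences among all 3 groups were tested with limma's F test. A positive difference means higher in the group named first.

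The choice of model, of 36 gene lists and of the genes to be named was made before the data were examined. The lists hold markers of skin and leukocyte cell types and pathways discussed for urticaria. They have 668 members, of which 617 were measured, and some genes stand in several lists. Lists were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 36 lists of a comparison, and again with an estimated correlation and with fry. The estimate takes account of genes that vary together between donors, which raises the p of lists of cell type markers. The test with an estimate also gave a larger p where the estimate was near the preset value. For prostaglandins and leukotrienes (lesional against nonlesional, estimate 0.015) camera's unadjusted p went from 0.000482 to 0.00428. A call lost with an estimated correlation is thus not by itself a sign of genes that vary together. The genes named were the 12 with the largest positive and the 8 with the largest negative difference among called genes, leaving out unnamed and small-RNA genes (where fewer than 10 genes passed, the 10 with the smallest p), up to 3 members with the smallest p in each called list, and 12 genes fixed in advance (SELE, ICAM1, IL6, CCL2, CXCL8, TPSAB1, CPA3, MS4A2, CLC, S100A8, IL33 and TSLP). Other members of a list are named only as examples of it, chosen after their values were seen. Lists added later, after the data were seen, were adjusted over the added lists of a comparison alone.

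Lesional and nonlesional biopsies with the same number came from the same patient, per the labels. The deviations of the 2 biopsies of a patient from their group means correlated between 0.139 and 0.615 in the 6 pairs, each over 0.1, so the numbers pair the samples. The sources used here do not say whether the submitters' test was paired, so the main model had no block, and a fixed patient block over the 6 pairs and a random block over all arrays (correlation 0.235) were alternatives. The main model and its F test thus treated the 2 biopsies of a patient as independent. In the random-block fit lists were tested with cameraPR, a form of camera that takes the moderated statistics themselves, at the same preset correlation. A list call that changed there can thus come from the block or from this form of the test. Correlations between arrays of a group were between 0.9618 and 0.9911, and no 2 arrays held identical values.

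Alternatives were fits of only the groups compared, filters on low genes, a second quantile normalization, median centring, eBayes with trend and robust settings, no moderation, array weights, the mean of a gene's rows, all rows tested, leaving out each biopsy in turn, a 2-fold minimum, and an unadjusted p under 0.05 with at least 1.5-fold. Leaving out both biopsies of 1 patient, whose arrays stood apart in the correlations between arrays, was added after the data were seen, as was the patient block together with an estimated correlation.

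The model was tested on simulated arrays with the means and spreads of the 18383 genes, in which 200 genes were changed. For lesional against nonlesional skin it recovered 86.6% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 3-fold, with 9 false calls. For lesional against normal skin the figures were 80.6%, 94% and 95.5% with 13 false calls, and for nonlesional against normal skin 79.1%, 94% and 98.5% with 9 false calls. In 40 simulations of lists without correlation between genes, the raised list was called 40 times and 2 of 1400 other lists were called. The simulated spread was normal and independent between genes, so these shares describe arrays without the shared variation between genes that real biopsies have. Figures were drawn with matplotlib 3.10.9 and tables prepared with pandas 2.3.3 in Python 3.11.15.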

Results

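Gene expression was measured on 18 whole-transcript microarrays, each made from RNA of a skin biopsy. The arrays held 6 biopsies of active lesions of patients with chronic idiopathic urticaria, a disease of recurrent itchy wheals with no known external trigger. A further 7 biopsies came from unaffected skin of the patients (nonlesional skin), and 5 came from skin of healthy donors (normal skin). In 6 patients both kinds of biopsy were available. Values are deposited log2 expression, and the array medians lay between 4.62 and 4.67 over all 18 arrays. The number of arrays limits the precision of every difference given here. After reduction to genes, 18383 genes were compared among the groups, and 2501 of them differed among the 3 groups at an adjusted p under 0.05 in limma's F test.

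The first comparison asks what differs between an active wheal and unaffected skin of the patients. E-selectin (SELE), which endothelial cells display to catch passing leukocytes, rose from 4.22 ± 0.19 (SD, n = 7) in nonlesional to 8.57 ± 0.85 (SD, n = 6) in lesional skin, a log2 difference of 4.35 ± 0.27 (SE). The nonlesional level of SELE lay below the median of every array, near the low end where differences are compressed, so its difference can be understated. The monocyte-attracting chemokine CCL2 rose by 4.31 ± 0.29 (SE), and the hyaluronan-binding protein TNFAIP6 by 4.67 ± 0.55 (SE). All 3 were higher in the lesional biopsy of 6 of the 6 pairs, with adjusted p of 1.14e-07, 1.97e-07 and 2.34e-05. In limma's test 2606 genes passed an adjusted p under 0.05, of which 1940 were higher and 666 lower in lesional skin, and 829 of them differed at least 1.5-fold, 713 higher and 116 lower. With the patient as a block over the 6 pairs, 2172 genes were higher and 1030 lower.

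The other genes with the largest rises were S100A8, a calcium-binding protein of neutrophils, monocytes and stressed keratinocytes (3.66 ± 0.54, SE), thrombospondin 1 (THBS1, 3.45 ± 0.34), the pentraxin PTX3 (3.39 ± 0.65), the metalloreductase STEAP4 (3.12 ± 0.31), UAP1, an enzyme that makes UDP-N-acetylglucosamine (2.95 ± 0.34), tenascin C (TNC, 2.94 ± 0.46), the protease cathepsin L (CTSL, 2.92 ± 0.30), macrophage elastase (MMP12, 2.92 ± 0.30) and NAMPT, an enzyme of NAD synthesis (2.82 ± 0.26). Their adjusted p lay between 2.95e-06 and 0.00168. Nonlesional levels of PTX3 (3.90) and MMP12 (3.93) also lay below the array medians, so the sizes and ranks of their differences carry the limit given for SELE. The largest falls were smaller. Log2 differences were -2.14 ± 0.42 (SE) for LGR5, a marker of hair follicle stem cells, -1.74 ± 0.44 for the alcohol dehydrogenase ADH1B, -1.70 ± 0.25 for the iron exporter SLC40A1, -1.70 ± 0.30 and -1.43 ± 0.26 for the transporter genes ABCA6 and ABCA9, -1.33 ± 0.38 for MAMDC2, -1.32 ± 0.27 for selenoprotein P (SELENOP) and -1.31 ± 0.21 for TCP11L2. The adjusted p of these 8 genes lay between 0.000146 and 0.024, and each was lower in the lesional biopsy of 6 of 6 pairs. The call of MAMDC2 ended without lesional replicate 2, 4 or 6 (adjusted p of 0.0526, 0.0666 and 0.0672).

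In the NF-kB response list 15 of 19 measured members rose and none fell, 16 when adjusted over the list alone, with a median log2 difference of 0.62. Among them were ICAM1, an adhesion molecule (2.50 ± 0.28, SE), the early lymphocyte activation antigen CD69 (1.75 ± 0.13) and SOD2 (2.16). The list test gave an adjusted p of 1.74e-13 with the preset correlation and 0.0344 with an estimated correlation. The call was lost with the patient as a block together with an estimated correlation (adjusted p = 0.241). The IL-6 and STAT3 response list had 11 of 18 members higher and none lower, 15 adjusted over the list alone. The oncostatin M receptor OSMR rose by 2.21 ± 0.19, STAT3 itself by 1.21 ± 0.12 and SOCS3, a feedback inhibitor of cytokine signalling, by 1.21. This list's adjusted p was 7.89e-11, and it was 0.0514 with an estimated correlation. IL6 rose by 1.79 ± 0.44 (adjusted p = 0.00986) and CXCL8, the neutrophil-attracting chemokine, by 0.71 ± 0.18 (adjusted p = 0.0119). The call of CXCL8 was lost over the 6 pairs without a block (adjusted p = 0.0573). Immediate early genes had 11 of 25 members higher and none lower, 14 adjusted over the list alone, with MYC (1.68), CCN1 (1.26 ± 0.17) and JUNB (0.93 ± 0.13) among them. Their list adjusted p was 6.19e-06, and 0.266 with an estimated correlation. Of the innate sensing list 9 of 22 members rose and 1, TLR3, fell (10 and 1 adjusted over the list alone), with MYD88 (0.73 ± 0.11), NOD1 (0.68 ± 0.10) and CASP4 (0.62 ± 0.09) having the smallest p. That list had an adjusted p of 0.000198, and 0.266 with an estimated correlation. By contrast, the inflammatory cytokine list as a whole was not called (adjusted p = 0.316). Of its 27 members 4 rose, namely IL6, IL1B (0.39), IL10 (0.23, adjusted p = 0.0399, and 0.134 with the patient as a block) and CSF1 (0.66), and TNF had a log2 difference of 0.10 (adjusted p = 0.121).

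In the leukocyte-endothelial adhesion list 11 of 19 members rose and 1 fell (13 and 2 adjusted over the list alone). VCAM1 rose by 2.32 ± 0.25, P-selectin (SELP) by 1.20 and the integrin gene ITGAX by 0.91, while CD34 fell by 1.24. This gave an adjusted p of 2.94e-06, and 0.261 with an estimated correlation. Neutrophil markers had 10 of 18 members higher and none lower, 13 adjusted over the list alone, with the formyl peptide receptors FPR1 (1.08 ± 0.22) and FPR2 (1.41 ± 0.34) and TREM1 (1.18 ± 0.23) leading. Their list adjusted p was 2.37e-06, and 0.341 with an estimated correlation. Of the monocyte and macrophage markers 4 of 18 rose and none fell, and 10 rose and 1 fell when adjusted over the list alone. The mannose receptor MRC1 rose by 1.98 ± 0.40, versican (VCAN) by 1.67 ± 0.38 and ficolin 1 (FCN1) by 0.66 ± 0.19, whereas C1QB and VSIG4 had log2 differences of -0.11 (adjusted p = 0.701) and -0.50 (adjusted p = 0.0668). With the patient as a block over the 6 pairs VSIG4 was called, at -0.63 (adjusted p = 0.0135), and over these pairs without the block its adjusted p was 0.0162. FCN1 lost its call without nonlesional replicate 1 or 4 or lesional replicate 7 (adjusted p of 0.0544, 0.0566 and 0.0656), after a second quantile normalization (0.0691), with only both groups in the model (0.0611) and over the 6 pairs without a block (0.104). For the list the adjusted p was 0.0103, and its call was lost with an estimated correlation (0.706), by fry (0.124), with the patient as a block over the 6 pairs (0.0571), over these pairs without the block (0.0841) and without nonlesional replicate 8 (0.0997). It was also lost with a random block (0.053, by cameraPR) and without the genes of lowest mean level, whether the lowest 25% (0.0561) or all under the median (0.104). Chemokines had 8 of 30 members higher and none lower, the same number adjusted over the list alone, including CCL19 (1.91 ± 0.34), which attracts T and dendritic cells, and CCL8 (0.89 ± 0.16). For chemokines the adjusted p was 0.00193, and 0.379 with an estimated correlation. Markers of other leukocytes were not called as lists, with adjusted p of 0.831 for mast cells, 0.316 for eosinophils and basophils, 0.231 for dendritic and Langerhans cells, 0.316 for T cells, 0.316 for NK and cytotoxic cells and 0.322 for B and plasma cells. In nonlesional skin the mean levels of the eosinophil and basophil list (4.39) and the T cell list (4.27) lay below the array medians. Changes in these lists can therefore be understated.

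Lipid mediator, clotting and type 2 genes changed in part. Of the prostaglandin and leukotriene list 9 of 21 members rose and none fell, also 9 adjusted over the list alone. They included ALOX5 (0.93 ± 0.16), the enzyme that starts leukotriene synthesis, its partner ALOX5AP (0.87 ± 0.20, adjusted p = 0.00589, and 0.0524 with the patient as a block) and the prostaglandin receptor PTGER4 (0.40 ± 0.09). With the patient as a block 6 members were higher and 1, HPGDS, lower (-0.54, adjusted p = 0.0328). The list adjusted p was 0.00217, but 0.0514 with an estimated correlation and 0.133 without genes under the median mean level. In the coagulation and fibrinolysis list 6 of 19 rose and none fell (7 and 1 adjusted over the list alone). Besides THBS1 these were SERPINE2 (2.45 ± 0.41), PLAUR (0.80 ± 0.13), PLAU, PLAT and THBD. The patient block gave 7 members higher and 2 lower, the tissue factor gene F3 being called at 0.40 (adjusted p = 0.0101), its inhibitor TFPI at -0.66 (0.000945) and VWF at -0.63 (0.0166). The list adjusted p was 0.0103, and the call was lost with an estimated correlation (0.379), without genes under the median mean level (0.0615) and over the 6 pairs with the block (0.0598) and without it (0.0606). Of 22 type 2 immunity genes 7 rose and none fell (9 adjusted over the list alone), led by the receptors IL4R (1.46 ± 0.20) and IL1RL1 (1.29 ± 0.20), which binds IL-33, and by CISH (0.58 ± 0.11). Its adjusted p was 0.0284, and the call was lost with an estimated correlation (0.266), without genes under the median mean level (0.379) and over the 6 pairs with the block (0.245) and without it (0.0841). Without nonlesional replicate 8, lesional replicate 2 or both biopsies of replicate 3 it was 0.0643, 0.0505 and 0.0628. The type 2 cytokine genes did not pass, with log2 differences of 0.01 for IL4, -0.04 for IL5, -0.02 for IL13, -0.21 ± 0.20 for IL33 (adjusted p = 0.565) and 0.00 ± 0.04 for TSLP (adjusted p = 0.982). The mast cell carboxypeptidase CPA3 had a log2 difference of -0.59 ± 0.31 (adjusted p = 0.246). With the patient as a block it was -0.78 (adjusted p = 0.0207), lower in lesional skin in 5 of 6 pairs. The eosinophil gene CLC had 0.23 ± 0.12 (adjusted p = 0.261). Nonlesional levels of CLC (3.92) and TSLP (3.79) lay below the 10% quantile of the genes tested (mean of 3.941 in nonlesional skin). A difference near 0 there can come from a gene that was not detected, so it does not show that the gene is unchanged. Levels of IL4, IL5 and IL13 are not given here, so their differences do not show that these genes are unchanged either. In the histamine and vasoactive list, which was not called (adjusted p = 0.0853), the histamine receptors HRH1 (0.74) and HRH2 (0.32) rose and the histamine-degrading enzyme HNMT fell by 0.32. That list was called after a second quantile normalization (adjusted p = 0.0311), with all probe sets tested (0.0267) and without lesional replicate 1, 2, 4 or 6 (0.0476, 0.0429, 0.0444 and 0.0327).

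In limma's model of all 18 arrays no list of the skin's own structures was called. The adjusted p was 0.666 for epidermal differentiation, where 1 of 22 members, the basal keratin KRT15, fell by 1.26 (3 members higher and 2 lower with the patient as a block, the list then leaning higher at an adjusted p of 0.428), and 0.631 for endothelial identity, where the VEGF receptors KDR (0.92) and FLT1 (0.56) rose and CLDN5 fell by 0.16. With the patient as a block 3 endothelial members were higher and 5 lower. Among the lower were PECAM1 (-0.80, adjusted p = 0.00221, lower in 6 of 6 pairs), VWF and TIE1 (-0.18, adjusted p = 0.0165), while the call of CLDN5 was lost (0.0516). With this block over the 6 pairs, 3 lists were lower in lesional skin, namely fibroblast and extracellular matrix (adjusted p = 0.189 without and 0.000728 with the block), sweat gland (0.231 and 0.00307) and sebaceous gland (0.322 and 0.0433). Their median log2 differences were -0.29, -0.58 and -0.43 without the block, where no member was called. With the block they were -0.43, -0.54 and -0.51, with 10 of 18, 4 of 10 and 0 of 13 members called, all lower. With an estimated correlation none of these lists was called, at adjusted p of 0.8, 0.783 and 0.896 without the block and 0.6, 0.481 and 0.753 with it. The fibroblast and extracellular matrix list was also called over the 6 pairs without the block (adjusted p = 0.0324), with array weights (0.0415) and without nonlesional replicate 8, lesional replicate 3 or both biopsies of replicate 3 (0.0248, 0.0153 and 0.042), and the sebaceous gland list without lesional replicate 4 (0.0192).

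Interferon response (adjusted p = 0.959), cell proliferation (0.338), complement (0.631), stressed keratinocyte genes (0.08), antimicrobial peptides (0.313) and glucocorticoid response genes (0.42) were not called. Of these, stressed keratinocyte genes were called after a second quantile normalization (adjusted p = 0.0362), with array weights (0.0415), with all probe sets tested (0.025) and without lesional replicate 1, 2 or 6 (0.018, 0.0352 and 0.0499), and glucocorticoid response genes by fry (0.0391). The remaining lists, also not called, were adipocyte (0.611), muscle (0.344), hair follicle (0.113), melanocyte (0.768), nerve (0.316) and erythrocyte and platelet markers (0.677). The hair follicle list was called, lower in lesional skin, without nonlesional replicate 3 or 4 or normal replicate 13 (adjusted p of 0.0492, 0.0464 and 0.0185) and with only both groups in the model (0.0197).

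In total, 11 of 36 lists were called in this comparison, all higher, and 1 was called with an estimated correlation. With the block and an estimated correlation 0 were called, the smallest adjusted p being 0.241. With the block 1 member each was called lower in the chemokine, type 2 and inflammatory cytokine lists, and 3 in the adhesion list. Among 100 splits of the same samples 49 called at least 11 lists with the preset correlation, so the number of called lists does not separate lesional from nonlesional skin. These splits ignored the pairing of biopsies, and lists were not counted for swaps within pairs. Of the 2606 called genes 74.4% were higher in lesional skin, but after a second quantile normalization the figure was 57.5% of 2761, with 1588 higher and 1173 lower.

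**Figure D1:**
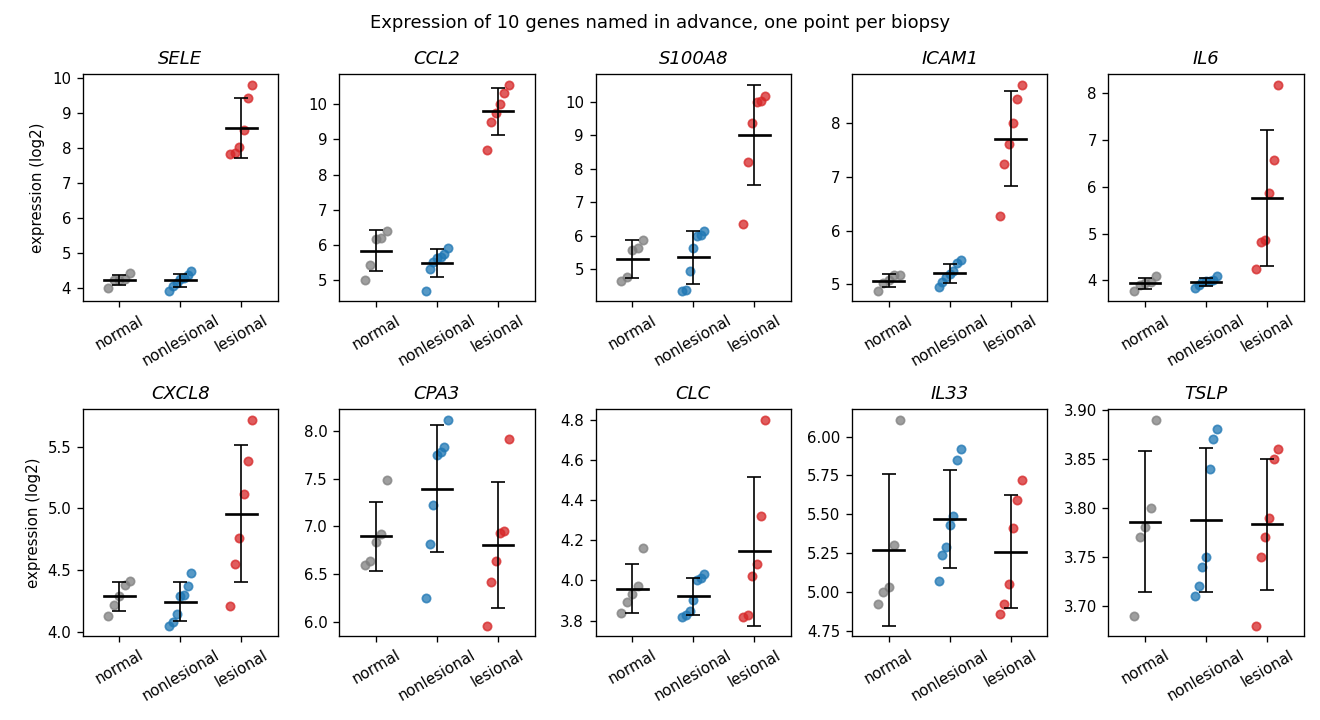
Expression of 10 genes named before the data were examined, with log2 expression on the vertical axis (scaled separately for each gene), one point per biopsy, the bar at the group mean and whiskers of 1 SD for 5 normal, 7 nonlesional and 6 lesional biopsies. Lesional means of SELE, CCL2 and S100A8 were 8.57, 9.80 and 9.01 against 4.22, 5.49 and 5.35 in nonlesional skin, while CPA3, CLC, IL33 and TSLP did not pass the test without a patient block. With the block CPA3 was called lower in lesional than in nonlesional skin (limma adjusted p = 0.0207). Group means of CLC and TSLP all lay below the array medians.

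The second comparison sets active lesions against skin of healthy donors, none of whom gave a lesional sample. TNFAIP6 rose by 5.05 ± 0.60 (SE; 4.51 ± 0.20 SD in normal skin, n = 5), SELE by 4.33 ± 0.29, THBS1 by 4.09 ± 0.37, CCL2 by 3.97 ± 0.31 and S100A8 by 3.72 ± 0.59, with adjusted p of 4.91e-05, 3.24e-07, 5.53e-06, 1.34e-06 and 0.000524. STEAP4, PTX3, TNC, CTSL and UAP1 rose by 3.37, 3.35, 3.34, 3.30 and 3.04. Serglycin (SRGN), a proteoglycan of leukocyte granules, rose by 3.30 ± 0.39, and the metallothionein MT1M by 2.96 ± 0.26. In limma's test 2312 genes passed, 1530 higher and 782 lower in lesional skin, and 868 of them differed at least 1.5-fold, 692 higher and 176 lower.

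The largest falls were in FABP7, a fatty acid binding protein (-1.89 ± 0.52), the basal keratin gene KRT15 (-1.80 ± 0.37), ADH1B (-1.74 ± 0.48), LGR5 (-1.66 ± 0.46), SLC40A1 (-1.64 ± 0.27), PSG4 (-1.36 ± 0.27), ABCA10 (-1.28 ± 0.16) and SOSTDC1 (-1.20 ± 0.25), with adjusted p between 9.49e-05 and 0.0243. For 3 of these genes leaving out 1 biopsy ended the call. It ended for FABP7 without lesional replicate 7 or normal replicate 12 or 15 (adjusted p of 0.0557, 0.0611 and 0.0536), for ADH1B without lesional replicate 4 or normal replicate 11, 12 or 14 (0.0555, 0.0576, 0.0722 and 0.052) and for LGR5 without normal replicate 11 or 15 (0.0726 and 0.0618).

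Signalling lists were called as in the first comparison. The NF-kB response list had 15 of 19 members higher and none lower, 16 adjusted over the list alone (adjusted p = 2.09e-13, and 0.0352 with an estimated correlation), with ICAM1 (2.64 ± 0.30) and CD69 (1.81 ± 0.15). The IL-6 and STAT3 list had 12 of 18 higher and none lower, 13 adjusted over the list alone (adjusted p = 1.06e-11, and 0.0391 with an estimated correlation), with OSMR (2.48 ± 0.21) and SOCS3 (1.29 ± 0.19). IL6 had a difference of 1.82 ± 0.47 (adjusted p = 0.0167), and its call was lost with only both groups in the model (adjusted p = 0.0754). CXCL8 had 0.67 ± 0.20 (adjusted p = 0.0307), and its call ended without lesional replicate 3, 4 or 7 (adjusted p of 0.0557, 0.0551 and 0.0756), without normal replicate 11, 12, 13 or 15 (0.0567, 0.0509, 0.0702 and 0.0628) and with only both groups in the model (0.0953). Innate sensing had 11 higher and 1 lower of 22, 12 and 1 adjusted over the list alone (adjusted p = 7.8e-06, and 0.188 with an estimated correlation). Immediate early genes had 9 of 25 higher and none lower, 10 adjusted over the list alone (adjusted p = 9.02e-07, and 0.195 with an estimated correlation).

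Of the monocyte and macrophage markers 10 of 18 rose and none fell, 11 adjusted over the list alone, with MRC1 (2.59 ± 0.43), VCAN (2.45 ± 0.41), lysozyme (LYZ, 2.42) and CD14 (1.30). The list adjusted p was 2.69e-07, and 0.292 with an estimated correlation. Leukocyte-endothelial adhesion had 13 of 19 members higher and none lower, 13 higher and 1 lower adjusted over the list alone (adjusted p = 6.75e-10, and 0.0878 with an estimated correlation). Neutrophil markers had 10 of 18 higher and none lower, 13 adjusted over the list alone (adjusted p = 4.82e-08, and 0.214 with an estimated correlation). Chemokines had 7 of 30 higher and none lower, 8 adjusted over the list alone (adjusted p = 9.1e-05, and 0.214 with an estimated correlation). Markers of dendritic and Langerhans cells had 3 of 14 higher, also 3 adjusted over the list alone, with CD1C at 0.99 ± 0.26 (adjusted p = 0.0278, and 0.312 with an estimated correlation). NK and cytotoxic markers had 3 of 13 higher, 4 adjusted over the list alone, with granzyme B (GZMB) at 0.95 ± 0.19 (adjusted p = 0.0393, and 0.52 with an estimated correlation). Complement genes had 4 of 20 higher, 6 adjusted over the list alone, among them the anaphylatoxin receptors C3AR1 (1.30 ± 0.29) and C5AR1 (0.35 ± 0.08), at an adjusted p of 0.0121 and of 0.574 with an estimated correlation.

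Genes of histamine, lipid mediators, clotting and type 2 immunity followed. The histamine and vasoactive list had 5 members higher and 1 lower of 21, 7 and 1 adjusted over the list alone, including HRH1 (0.75 ± 0.18), HRH2 (0.37 ± 0.09) and HDC, the enzyme that makes histamine (0.77 ± 0.22, adjusted p = 0.0308). HDC lost its call without lesional replicate 3, 4 or 7 (adjusted p of 0.0582, 0.0613 and 0.0754) or normal replicate 12, 13, 14 or 15 (0.0748, 0.0702, 0.0557 and 0.0624). The list's adjusted p was 0.0121, and 0.427 with an estimated correlation. Prostaglandins and leukotrienes had 7 of 21 higher and none lower, 9 and 1 adjusted over the list alone (adjusted p = 0.00896, and 0.102 with an estimated correlation). Coagulation and fibrinolysis had 6 of 19 higher and none lower, 9 adjusted over the list alone (adjusted p = 0.00178, and 0.214 with an estimated correlation), and type 2 immunity 7 of 22 higher and none lower, also 7 adjusted over the list alone (adjusted p = 0.00956, and 0.188 with an estimated correlation). Neither CPA3 (-0.09 ± 0.34, adjusted p = 0.911), CLC (0.19 ± 0.13, adjusted p = 0.424), IL33 (-0.02 ± 0.22, adjusted p = 0.978) nor TSLP (0.00 ± 0.05, adjusted p = 0.98) passed. CLC and TSLP carry the limit of low levels given for them above.

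Lower in lesional than in normal skin were 3 lists. Epidermal differentiation had 1 of 22 members called, KRT15, the same adjusted over the list alone, and a median log2 difference of -0.44 (adjusted p = 0.00124, and 0.574 with an estimated correlation). Its members FLG2 (-0.73, adjusted p = 0.0511) and LCE2B (-0.91, adjusted p = 0.0526) missed the threshold but were called in 11 and 9 alternatives, with adjusted p between 0.0089 and 0.116 and between 0.0146 and 0.111 over all of them. Leaving out lesional replicate 1 or nonlesional replicate 3 called both genes (0.0089 and 0.027 for FLG2, 0.0146 and 0.042 for LCE2B), leaving out nonlesional replicate 7 or 8 called FLG2 (0.0493 and 0.0433), and leaving out lesional replicate 6 called LCE2B (0.0493). The adipocyte list had a median of -1.02 (adjusted p = 0.0121, and 0.574 with an estimated correlation) and the hair follicle list a median of -0.84 (adjusted p = 0.0356, and 0.601 with an estimated correlation), with no member of either called over all genes or over the list alone. The call also ended, without 1 biopsy, for 6 of the called lists. These were dendritic cells without normal replicate 12 (adjusted p = 0.052) or lesional replicate 1 or 2 (0.0508 and 0.0512), NK cells without lesional replicate 2 or 3 or normal replicate 12 or 13 (0.0985, 0.0706, 0.052 and 0.103), and complement without lesional replicate 3 or normal replicate 12 or 13 (0.0671, 0.052 and 0.0537). The others were histamine mediators without lesional replicate 3 (0.0671), adipocytes without lesional replicate 1 or normal replicate 11 or 12 (0.0508, 0.0546 and 0.0541), and hair follicle without lesional replicate 1, 2 or 3 or normal replicate 11 or 13 (0.0508, 0.0601, 0.0671, 0.0592 and 0.466). The hair follicle call was also lost with array weights (0.0571).

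Of the remaining lists none was called in limma's model of all 18 arrays, including mast cell markers (adjusted p = 0.0784), T cell markers (0.0546), interferon response (0.145) and fibroblast and extracellular matrix (0.856). T cell markers were called in 11 alternatives. These were a second quantile normalization (adjusted p = 0.0143), median centring (0.0395), all probe sets tested (0.0283), only both groups in the model (0.0327), and leaving out lesional replicate 1, 4, 6 or 7 (0.0232, 0.0362, 0.0442 and 0.0362), nonlesional replicate 2 or 8 (0.0487 and 0.0401) or normal replicate 11 (0.0306). Mast cell markers were called in 4, with all probe sets tested (0.0437) and without lesional replicate 4 or 6 or normal replicate 11 (0.0315, 0.0332 and 0.0404). Over all alternatives the adjusted p reached 0.574 for T cell and 0.591 for mast cell markers. Leaving out 1 biopsy also brought the call of proliferation genes (0.0384, 0.0433, 0.0348 and 0.042 without lesional replicate 1 or 2 or normal replicate 11 or 12), stressed keratinocyte genes (0.0323, 0.0478 and 0.0335 without lesional replicate 1 or 2 or normal replicate 14), inflammatory cytokines (0.0295 without lesional replicate 4), antimicrobial peptides (0.0232 without lesional replicate 1), sweat gland markers (0.0323 without normal replicate 14) and melanocyte markers (0.0413 without lesional replicate 2).

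In all 18 lists were called, 15 higher and 3 lower, and 2 with an estimated correlation. Among 100 splits of these samples 21 called at least as many lists with the preset correlation. Of the called genes 66.2% were higher, and 55.8% after a second quantile normalization, with 1418 higher and 1121 lower.

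**Figure D2:**
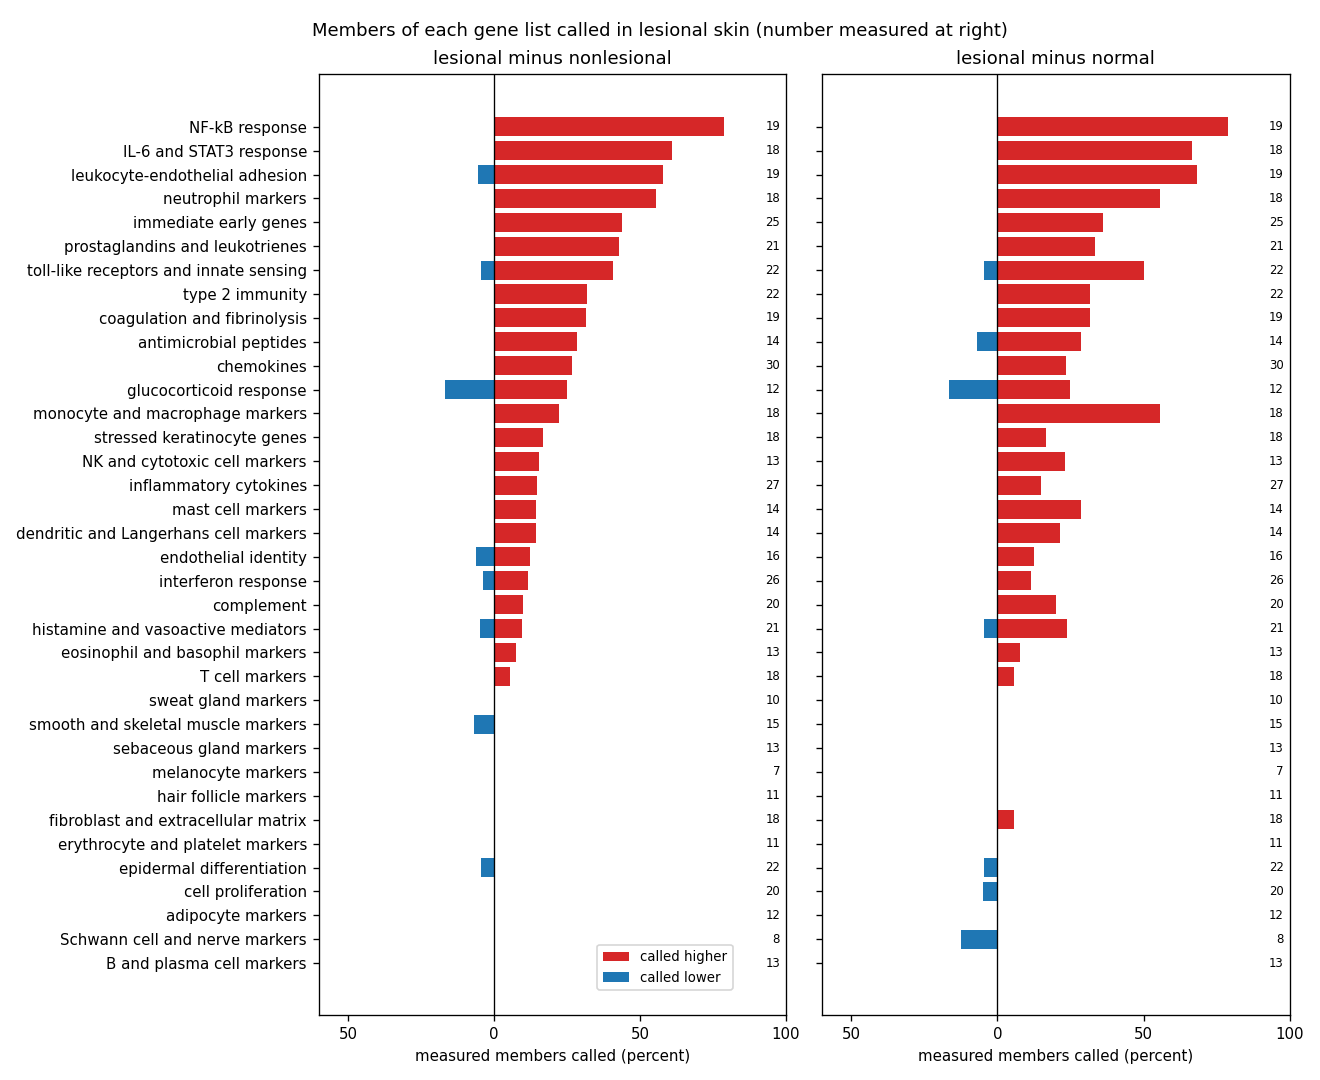
Percent of the measured members of each of 36 gene lists that were called at an adjusted p under 0.05, higher (red, to the right) or lower (blue, to the left) in lesional skin, against nonlesional skin in the left panel and normal skin in the right panel, with the number of measured members at the right edge. In the NF-kB response list 15 of 19 members were higher in both comparisons, and in the monocyte and macrophage list 4 of 18 against nonlesional and 10 of 18 against normal skin.

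The third comparison asks whether unaffected skin of the patients differs from normal skin. Nearly no gene separated these groups. In limma's test 1 of 18383 genes passed, CCDC125, a coiled-coil gene, at 5.20 ± 0.07 (SD, n = 7) in nonlesional and 5.55 ± 0.11 (SD, n = 5) in normal skin, a difference of -0.36 ± 0.05 (SE; adjusted p = 0.0165). In the normal group 1 biopsy lay far below the others for this gene. Its call ended without nonlesional replicate 6 or 8 (adjusted p of 0.0586 and 0.0504) and without normal replicate 11, 12, 13 or 15 (0.0654, 0.103, 0.104 and 0.0545). No gene passed with at least a 1.5-fold difference, and 897 had an unadjusted p under 0.05, where chance alone would give 919. The gene with the next smallest p, the epidermal gene RPTN, had a difference of -0.60 ± 0.10 and failed the test (adjusted p = 0.0916). It passed without normal replicate 14 (adjusted p = 0.0195) and with trend and robust settings (0.0492), and over all alternatives its adjusted p lay between 0.0195 and 0.81.

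Of the genes fixed in advance, none was called between nonlesional and normal skin. SELE differed by -0.02 ± 0.28 (SE), ICAM1 by 0.14 ± 0.29, CCL2 by -0.35 ± 0.30, S100A8 by 0.05 ± 0.57, IL6 by 0.03 ± 0.46 and CXCL8 by -0.04 ± 0.19, with adjusted p between 0.927 and 0.998. The mast cell gene CPA3 (0.50 ± 0.33), the eosinophil gene CLC (-0.04 ± 0.13) and the alarmin genes IL33 (0.20 ± 0.21) and TSLP (0.00 ± 0.04) did not pass either (adjusted p between 0.915 and 1). For CLC and TSLP the limit of low levels given above holds here too. Among other genes that rose in lesions, VCAN and SRGN had differences of 0.78 ± 0.40 and 0.73 ± 0.38, each with an adjusted p of 0.915.

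With the preset correlation 13 lists were called between nonlesional and normal skin, although none of their members was called over all genes or over the list alone. None was called with an estimated correlation, where the adjusted p of each of the 36 lists was at least 0.697, and none by fry. Higher in nonlesional skin were monocyte and macrophage markers (median 0.34, adjusted p = 9.99e-08), complement (0.18, adjusted p = 0.000187), leukocyte-endothelial adhesion (0.14, adjusted p = 0.000594), fibroblast and extracellular matrix (0.25, adjusted p = 0.00131), mast cell markers (0.08, adjusted p = 0.00251) and interferon response (0.08, adjusted p = 0.00613). Endothelial identity (adjusted p = 0.0207), B and plasma cells (0.0373), sebaceous gland, NK cells and erythrocytes and platelets (each 0.0475) were also higher. Lower were epidermal differentiation (median -0.44, adjusted p = 2.51e-07) and adipocyte markers (median -0.87, adjusted p = 0.000952). In these lists the members with the smallest unadjusted p included COL6A3 (0.69 ± 0.23), ALOX12B (-0.66 ± 0.27), MS4A6A (0.60 ± 0.25), CMA1 (0.55 ± 0.22) and PLIN1 (-1.40 ± 0.66), each with an adjusted p of 0.915. Among 100 splits of these 12 samples 19 called at least 13 lists.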

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

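Of the tests in this part, those on ribosome biogenesis genes over the pairs, on HBB, on resident macrophage markers and on circulating monocyte markers were chosen after the result was seen, and the others before. The other tests on ribosome biogenesis genes were chosen before their own outcome was seen, but on a list written after its genes had drawn attention.

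Genes of ribosome biogenesis were higher in lesional than in nonlesional skin, a list written after these genes had drawn attention and tested without PNO1 and BYSL, the genes that had done so. Of 48 measured members 46 rose and none fell, with a median log2 difference of 1.04, and the list mean was higher in 6 of 6 pairs by 1.05 ± 0.26 (SD, two-sided exact sign-flip p = 0.0312, the smallest that 6 pairs can give). Against a shift of all genes at the same expression level, 0 of 10000 random lists matched on mean expression had a median as large (highest 0.23). Against a difference in the signal distribution between arrays, the median was 0.98 after a second quantile normalization. Genes of a random list need not vary together as genes of 1 process can, so the count of such lists does not measure chance. No biological explanation was tested, and a change in which cells the biopsies hold also stays open.

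More genes were higher than lower in lesional skin, 1940 against 666 of those called. The imbalance was larger among genes with larger differences, 713 against 116 at 1.5-fold or more and 231 against 15 at 2-fold or more. Over the genes tested, an array's upper quartile was itself higher in the lesional biopsy of 6 of 6 pairs. Its means were 6.022 ± 0.056 (SD) in lesional, 5.928 ± 0.057 in nonlesional and 5.974 ± 0.057 in normal skin. These means lie closer together than the 1.5-fold minimum, a log2 difference of 0.585. A shift of that size would not by itself bring an unchanged gene to this minimum. After a second quantile normalization 57.5% of called genes were higher, against 74.4% before. The arrays differed in the upper part of the signal distribution and not over its whole range. The 90% quantile was also higher in lesional skin in 6 of 6 pairs (means of 7.566 in lesional and 7.447 in nonlesional skin). The median was higher in 0 pairs (4.650 and 4.653) and the 25% quantile in 3. This difference in the upper part may account for much of the imbalance in the count without a fold minimum. The second quantile normalization would also remove part of a true one-sided change, so whether the difference is technical stays open.

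Of 18 neutrophil markers 10 were called higher in lesional skin, and 4 of 18 monocyte and macrophage markers, but with an estimated correlation neither list was called (adjusted p of 0.341 and 0.706, and 0.6 and 0.712 with the patient block). More whole blood in the lesional biopsies cannot be told apart from cell entry, because HBB, the most abundant blood transcript measured, varied widely. Its difference was -0.46 ± 0.79 (SE), with an upper 95% limit of 1.21 against the neutrophil list's median of 0.50, and it was higher in lesional skin in 2 of 6 pairs. None of the 11 measured erythrocyte and platelet genes was called. Upper 95% limits of HBD, ALAS2 and PF4 (0.21, 0.15 and 0.21) lay below that median and that of PPBP (0.72) above it. Nonlesional levels of these 4 genes (4.25, 4.26, 4.78 and 4.43) lay near or below the array medians, where differences are compressed, so they do not settle it. More macrophages of every kind cannot be told apart either, since the mean of 9 resident macrophage markers differed by -0.05 ± 0.22 (SD over 6 pairs) and was higher in 3 of them. These 9 moved both ways, with CD163 higher in 5 pairs and C1QB in 1. The list was tested without VSIG4, C1QA, LYVE1 and SELENOP, which had drawn attention to it. Their log2 differences were -0.50, -0.23, -0.70 and -1.32, and they were higher in 0, 1, 0 and 0 pairs. SELENOP was called (adjusted p = 0.00304), and with the patient as a block so were VSIG4 (0.0135) and LYVE1 (0.0271). A list of 11 circulating monocyte markers had 7 members higher and a mean of 0.52 ± 0.32 (SD, 6 of 6 pairs). However, its adjusted p with an estimated correlation was 0.123, adjusted over only the lists added after the data were seen. Of the 7 members, 3 (S100A12, CSF3R and FPR1) also stand in the neutrophil list. The circulating monocyte list was tested without MRC1, VCAN, FCN1, S100A8 and CLEC4A, which had drawn attention to it. Each of these rose and was higher in 6 of 6 pairs. MRC1 (1.98), from the monocyte and macrophage list chosen in advance, is not among the resident markers. The means of both added lists thus depend on how genes were sorted after their values were seen. Entry of blood monocytes and neutrophils stays open.

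Other splits of the samples bear on the counts of called genes and lists. For lesional against nonlesional skin chance can be excluded, at 1 in 100, for the number of called genes (2606). Only 1 of 100 splits, the real one, gave as many. The highest other gave 1764 and differed from the real one by 1 lesional biopsy. These splits ignored the pairing. They bear on the count and not on single genes, some of which pass an adjusted p under 0.05 by chance. Among the 64 swaps of labels within pairs only the real one, 1 of them, gave as many, and the highest other, with 1795, swapped all 6 pairs and so mirrors it. Chance can be excluded in the same sense for the number of genes of lesional against normal skin (2312, 1 of 100 splits, highest other 531). The same holds for the number of the F test (2501, 1 of 100, highest other 1), where the regroupings also ignored the pairing. For nonlesional against normal skin 1 of 100 splits, the real one, gave as many as 1 gene (highest other 0), but with a single gene at the threshold this does not exclude chance. Its call was lost in 11 alternatives, with adjusted p up to 0.27, and fewer genes than chance gives had an unadjusted p under 0.05 (897 against 919). Chance cannot be excluded for the numbers of called lists with the preset correlation. The 11 lists of lesional against nonlesional skin were reached by 49 of 100 splits (highest other 22), the 18 of lesional against normal skin by 21 (highest other 27) and the 13 of nonlesional against normal skin by 19 (highest other 18). Lists were not counted for the swaps within pairs, so the pairing does not enter these counts.

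In 37 of 492 sets of values, each a gene, list mean or array median in 1 group, 1 biopsy lay far from the others, where chance alone gives about 1 in 20. The gap to the nearest other biopsy is given as a share of the group's range. Among list means the lowest biopsy stood apart for eosinophil (0.663), T cell (0.602) and chemokine lists (0.581) in nonlesional skin and for NK cell (0.91) and histamine lists (0.818) in normal skin. The highest biopsy stood apart for the NF-kB (0.721) and muscle lists (0.67) in nonlesional skin, the interferon (0.714) and sebaceous lists (0.641) in lesional skin, and the dendritic cell (0.787) and melanocyte lists (0.738) in normal skin.

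Among single genes, the lowest normal biopsy stood apart for CCDC125 (0.931) and CD22 (0.784), the lowest lesional one for MS4A6A (0.742), and the lowest nonlesional one for CCL19 (0.626), GVQW3 (0.682), PLAUR (0.603) and PRF1 (0.629). The highest normal biopsy stood apart for CASP4 (0.733), CCL19 (0.869), GZMB (0.74), HDC (0.721), KRT31 (0.885) and KRT35 (0.87). In lesional skin the highest stood apart for CIDEC (0.682), IFI6 (0.647), JCHAIN (0.65), LPL (0.629), PLIN1 (0.681) and SOSTDC1 (0.629), and in nonlesional skin for CCL8 (0.71), GBP4 (0.622), HDC (0.679), KRT75 (0.726), MC5R (0.664), SERPINE2 (0.718) and TNFAIP6 (0.571).

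Of 13745 probe sets without a single gene symbol, which no comparison above uses, limma called 595 between lesional and nonlesional skin, 457 higher and 138 lower. It called 372 between lesional and normal skin and 0 between nonlesional and normal skin, where 707 had an unadjusted p under 0.05.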

How the results depend on the processing

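Leaving out both biopsies of replicate 3, and the patient block together with an estimated correlation, were chosen after the data were seen, and the other alternatives before. Of 49 named genes called between lesional and nonlesional skin 45 kept their direction and call at an adjusted p under 0.05 in every other fit, filter and scaling run, as did 55 of 62 between lesional and normal skin, and no called gene reversed. The 1.5-fold and 2-fold minimums are not part of these counts, since some called genes differed by less. With the patient as a fixed block over the 6 pairs, 2172 genes were higher and 1030 lower. This fit also leaves out the unpaired nonlesional biopsy. It changed the call of 6 lists, given with it above, of which 4 (monocyte and macrophage, type 2, coagulation, fibroblast) changed over the 6 pairs without the block too. Of 621 genes named by rule or standing in a list it called 55 more and 18 fewer, and 20 of these 73 changed over the pairs without the block too. Among genes named above for that comparison, the calls of ALOX5AP, HPGDS, CPA3, VSIG4, LYVE1, IL10, CLDN5, F3, TFPI, VWF, PECAM1 and TIE1 changed and no other did. With the block and an estimated correlation 0 lists were called. A random block for the patient gave 2476 higher and 1115 lower, called FLG2 and LCE2B between lesional and normal skin (adjusted p of 0.0471 and 0.0412), as did the filters on low genes, a second quantile normalization, trend and robust settings and array weights, and ended the calls of dendritic cell, NK and hair follicle lists there (0.0566, 0.0715 and 0.0874), of the monocyte and macrophage list against nonlesional skin (0.053) and of NK and erythrocyte lists between nonlesional and normal skin (0.0532 and 0.0504). The list results with the random block came from cameraPR, so the block and the form of the test changed together. An unadjusted p with at least 1.5-fold gave 902, 1015 and 41 genes in the 3 comparisons, and a 2-fold minimum 246 and 254 in the first pair, both by construction. Lists called with an estimated correlation were 1, 2 and 0. Without genes under the median mean level 7 lists were called between lesional and nonlesional skin, and the calls of type 2 (0.379), prostaglandin (0.133), monocyte and macrophage (0.104) and coagulation lists (0.0615) ended. Against normal skin it ended those of dendritic cell (0.306), type 2 (0.145), histamine (0.128), hair follicle (0.125) and prostaglandin lists (0.0683), and fry those of NK (0.0672), complement (0.12), adipocyte (0.163), epidermal (0.182) and hair follicle lists (0.256), while fry called the antimicrobial and glucocorticoid lists there (0.0406 and 0.0412). The T cell, NK, B cell, eosinophil, erythrocyte and nerve lists kept too few members above the median mean level to be tested. For nonlesional against normal skin 0 genes were called without genes under the median mean level, after quantile normalization, with the mean of a gene's probe sets and with only 2 groups in the model, against 1 in limma and 897 at an unadjusted p under 0.05. Trend and robust settings gave 1 gene at 1.5-fold, fry called 0 lists and testing all probe sets 8. For these changes the cause was not tested.

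Leaving out 1 biopsy at a time, or both of replicate 3, gave 2040 to 2863, 1756 to 2813 and 0 to 2 genes in the 3 comparisons, with 2 without normal replicate 14 and 0 without nonlesional replicate 6. At 1.5-fold it gave 724 to 974, 717 to 1087 and 0 to 1. The lists called were 10 to 13, 14 to 21 and 8 to 17, with 8 without normal replicate 12 and 17 without nonlesional replicate 8. For the hair follicle list, lower and not called between nonlesional and normal skin (adjusted p = 0.527), the adjusted p ranged from 0.006493 to 0.9782, and without normal replicate 13 (0.006493) the list was higher in nonlesional skin, so its direction reversed and the cause was not tested. Camera was not run without moderation. Signals near the array background limit the differences that can be seen in low genes.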

Other observations

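The tests on lists in this part were chosen after the result was seen, except the adjustment for epidermis and fat and the comparison across patients. Genes named here beyond those named before were chosen after their values were seen.

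Among ribosome biogenesis genes the largest differences between lesional and nonlesional skin were those of the helicase DDX21 (2.29), RRS1 (1.79), UTP4 (1.73), NOLC1 (1.72) and the methyltransferase NOP2 (1.61), and FBL and IMP3 were not called. Against normal skin 44 of 48 members were higher (median 0.90), and between nonlesional and normal skin the median was -0.14 with none called. With an estimated correlation the list's adjusted p was 0.0069 against nonlesional and 0.0127 against normal skin. The adjustment was over the lists added after the data were seen, and not over those chosen in advance. The added lists are ribosome biogenesis, metallothionein and zinc transport, hyaluronan, resident macrophage, circulating monocyte and clock genes. Their adjusted p are therefore not on the same footing as those of the lists chosen in advance.

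Some metallothionein and zinc transport genes were also higher in lesional skin. MT1M, MT2A and SLC39A14, which drew attention to them, rose by 2.73, 1.99 and 2.79. Of 9 other members 5 rose, among them MT1G (1.33) and the zinc importer SLC39A8 (1.26), and the list mean was higher in 6 of 6 pairs by 0.57 ± 0.13 (SD, exact sign-flip p = 0.0312, the smallest possible). A coordinated rise may be present, although metallothionein genes are alike enough that probes could be shared between them. Hyaluronan genes beyond TNFAIP6, PTX3, UAP1 and VCAN had 4 of 11 members higher, namely the synthase HAS2 (2.17), CEMIP2 (1.71), UGDH (1.36) and the receptor CD44 (0.59). Their mean was higher in 6 of 6 pairs by 0.49 ± 0.17 (SD, exact p = 0.0312), but the median was 0.07 and the adjusted p with an estimated correlation 0.0757, so the possible rise rests on those 4 genes.

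Clock genes moved both ways. Apart from NR1D2 (-1.13), 3 of 15 were higher, CRY1 (0.52), CLOCK (0.41) and BHLHE40 (0.70), and 4 lower, DBP (-0.59), HLF (-0.64), PER1 (-0.47) and BHLHE41 (-0.30). The list mean was lower in 5 of 6 pairs by -0.11 ± 0.09 (SD, exact sign-flip p = 0.0625). A different hour of sampling cannot be told apart from other changes, because members that move in opposite directions leave a mean near 0.

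Monocyte and macrophage markers between nonlesional and normal skin had a mean difference of 0.36 ± 0.21 (SE). With each sample's epidermal and adipocyte list means as covariates it was 0.17 ± 0.25 (SE), 47.4% of the first value. Less epidermis and fat in the patients' biopsies may account for part of it, but the errors are as large as the change, so this cannot be told apart from a difference in the macrophages.

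Whether part of the lesional change is present in nonlesional skin was tested across patients. The 200 genes highest in the lesions of 3 pairs were compared between the other patients' nonlesional biopsies (n = 4) and normal skin (n = 5), and then with the pairs exchanged, the unpaired nonlesional biopsy being in both. The differences were 0.01 ± 0.11 (SE, exact permutation p = 0.968) and -0.05 ± 0.05 (SE, exact permutation p = 0.381), or 0.416% and -3.81% of the lesional change, over 126 splits each. Upper limits of 13.7% and 3.97% leave a small share open.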
